A study of Mus musculus with 20 samples.

How the data were processed

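Polyadenylated RNA of clonal ATDC5 lines was sequenced from 3 Kmt2d+/+ and 2 Kmt2d-/- clones at day 0 and day 7, giving 10 libraries in 4 groups. Each clone is a distinct cell line and a biological replicate, per the series' design. Per the labels' protocols, RNA was extracted with TRIZOL, messenger RNA was purified with poly(A) beads, and libraries were made with the NEBNext Ultra II kit. Differentiation medium contained insulin, transferrin and selenium with ascorbic acid and beta-glycerophosphate. Each library was run on 2 flow cells, so the table held 20 columns, and 0 columns were left unmatched to a sample.

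The deposited values were gene-level estimated counts, not normalized, for 27911 Ensembl genes. Only 0.351% of the nonzero values lay within 0.001 of a whole number. Per the submitters' processing notes, Salmon, edgeR, limma, DESeq2 and the GRCm38 build were used. Their versions, the transcript annotation and the way transcript estimates were summed to genes are not given in the sources used here. Whether the counting used strand is not given either, so reads of overlapping and antisense genes cannot be told apart. An estimated count splits reads between similar transcripts, and values of near-identical copies are therefore uncertain.

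The 2 runs of a library are technical repeats. Their log2 values correlated with r = 0.989 to 0.995 across genes, and they were summed and then rounded to whole numbers. Summed libraries held 35792709 to 66237183 counts. Between 13326 and 15016 genes had at least 10 counts, and mitochondrial genes took 1.98% to 2.93%. In the shallowest library a floor of 3 counts corresponds to 0.0838 CPM. Intervals and floors cover counting error only. Gene symbols and coordinates came from the GENCODE vM21 annotation of GRCm38, and 481 of the 27911 identifiers had no symbol.

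One edgeR model with a mean for each of the 4 groups was fitted to all 10 libraries (edgeR 4.0.16, R 4.3.3). It used filterByExpr, which kept 15467 genes, TMM scaling, and the quasi-likelihood F test with 6 residual degrees of freedom. The common biological coefficient of variation was 0.385. Comparisons were Kmt2d-/- against Kmt2d+/+ at day 7 and at day 0, day 7 against day 0 in each genotype, and the difference of the 2 day effects (interaction). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the log2 fold change and its F statistic. Group values are mean CPM with SD over clones, and folds are the model's estimates. For a gene with all counts at 0 in a group, the fold is a lower bound against 3 counts per library. With 1 to 3 counts in a group, the ratio of summed counts has an exact binomial 95% interval. Overlaps of calls and shares by chromosome were described with Fisher's exact test.

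Gene lists were tested with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists that had 5 or more measured genes. The 28 lists were cartilage matrix, chondrogenic transcription factors, hypertrophic and mineralizing chondrocyte genes, BMP and TGF-beta, hedgehog and PTHrP, FGF and Wnt signalling, H3K4 methyltransferase complexes, and markers of osteoblasts, adipocytes, skeletal muscle, myofibroblasts and smooth muscle, tendon and fibroblasts, endothelium, immune cells, epithelium, and neural and glial cells. The others were S phase, G2 and M phase, hypoxia targets, oxidative phosphorylation, cholesterol synthesis, interferon response, unfolded protein response, Hox genes, matrix proteases and inhibitors, p53 targets, and cytosolic ribosomal proteins. Of their 613 distinct genes 612 were matched, 2 through a synonym, and Hoxd4 was not. Counts adjusted over the list alone applied the Benjamini-Hochberg step to the list's members.

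Named genes followed a rule. It took Kmt2d, Shox2 and Sox9 in each comparison. It added the 10 largest positive and 10 largest negative log2 fold changes among passing genes with a mean of at least 5 CPM in a group, a named symbol and every clone of 1 group above every clone of the other. It then took up to 4 passing members of each list, or else its most abundant member, and the 5 smallest p where no gene passed. Some genes that the rule drew are not reported here. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

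Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors or upper-quartile scaling in edgeR, no filter, a mean of at least 5 CPM, glmTreat against a fold of 1.5, each flow-cell run alone, only the groups compared, a term for each clone, and each clone left out with both of its libraries. For lists they were an estimated correlation, DESeq2's size factors, a term for each clone and limma's fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. Chosen after the data were seen were the term for each clone with an estimated correlation, and a regional offset. That offset is each clone's running median deviation over the 25 expressed genes on either side along the chromosome. Window medians used 10 Mb windows with at least 10 expressed genes. The same cell lines were sampled at both days, which pairs libraries of a clone. The main fit does not model this pairing, so for the genotype comparisons its 6 residual degrees of freedom overstate the independent information between clones. Their deviations from the group means correlated with r = 0.446, 0.645 and 0.596 for Kmt2d+/+ clones 1, 2 and 3 over 10488 genes. Deviations within the 2 Kmt2d-/- clones mirror each other and gave 0.552.

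The tests were run first on simulated counts with genes changed by 2, 4, 8 or 16-fold. For the day 7 genotype comparison 8.16%, 55.1%, 69.4% and 76% of them were recovered (15313 genes tested), and for day 0 12%, 61.2%, 68% and 79.6% (15324 genes). For differentiation of Kmt2d+/+ clones 4%, 65.3%, 68% and 86% were recovered (15348 genes), for that of Kmt2d-/- clones 2.04%, 46.9%, 65.3% and 72% (15313 genes), and for the interaction 0%, 32.7%, 57.1% and 64% (15313 genes). A simulated 1.5-fold gain of a segment with 482 genes at day 7 gave a median log2 difference of 0.55, and -0.02 with the regional offset (15343 genes tested). Tables were handled with pandas 2.3.3 and numpy 2.4.6 and figures drawn with matplotlib 3.10.9.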

Results

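RNA-seq was used to compare Kmt2d-/- with Kmt2d+/+ clones of ATDC5, a mouse cell line that forms cartilage-like cells when cultured with insulin. The mutant clones carried deletions of the catalytic SET domain of Kmt2d on both alleles, per the labels. Kmt2d+/+ clones 1, 2 and 3 are named 10-5, 10-7 and 10-8 in the labels, and Kmt2d-/- clones 1 and 2 are named 10-7 and 96-9. Each of the 3 Kmt2d+/+ and 2 Kmt2d-/- clones was harvested undifferentiated (day 0) and after 7 days of chondrogenic differentiation (day 7). The resulting 10 libraries were each sequenced on 2 flow cells, and the runs of a library were summed. Summed depth ranged from 35792709 to 66237183 counts per library, and single runs held 13883415 to 35785488. The 10 most abundant genes took 11.1% to 12.8% of the counts in 3 of the 4 Kmt2d-/- libraries and 8.26% in that of clone 2 at day 0. In the Kmt2d+/+ libraries they took 6.19% to 7.65%. On the first principal component (40.9% of the variance) every clone had a higher score at day 7 than at day 0.

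Kmt2d (ENSMUSG00000048154), which encodes a histone H3 lysine methyltransferase mutated in Kabuki syndrome, lies on chromosome 15 at 98831669 to 98871204 (GRCm38). Its level in the Kmt2d+/+ clones 1, 2 and 3 was 210.8, 185.4 and 194.6 CPM (counts scaled to the TMM-adjusted library size) at day 0 and 186.7, 173.3 and 207.0 CPM at day 7. In the Kmt2d-/- clones 1 and 2 it was 205.2 and 148 CPM at day 0 and 174.8 and 113.3 CPM at day 7. The gene-level difference between genotypes did not pass the test at day 7 (log2 fold change -0.39, SE 0.22, edgeR adjusted p = 0.363) or at day 0 (-0.16, SE 0.22, edgeR adjusted p = 0.731). Counts over the whole gene do not measure the deleted part, so this level checks neither the labels nor the loss of the domain.

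**Figure D1:**
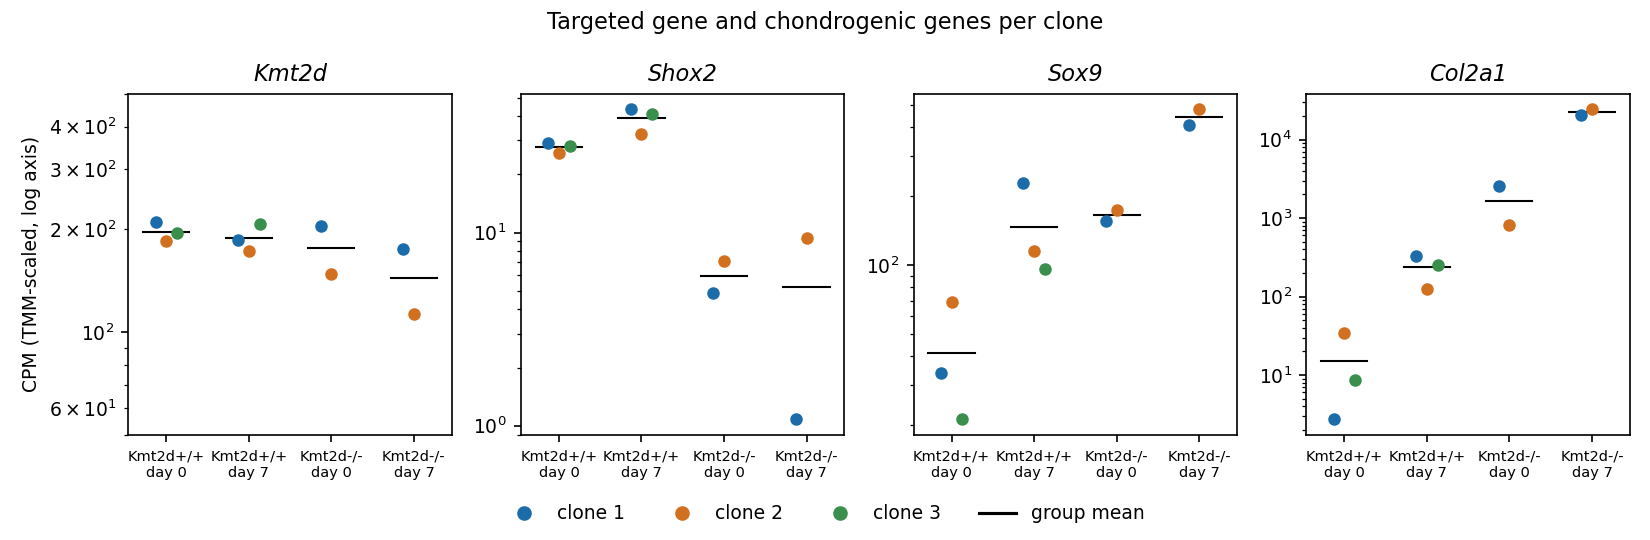
CPM on a log axis for Kmt2d, Shox2, Sox9 and Col2a1 in each library, by genotype and day, with points for clones and bars for group means. Col2a1 averaged 236.7 CPM in the 3 Kmt2d+/+ clones and 22460 CPM in the 2 Kmt2d-/- clones at day 7, while Kmt2d averaged 189 and 144 CPM.

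The first comparison asked which genes differed between Kmt2d-/- and Kmt2d+/+ clones at day 7. The 25 cartilage matrix genes had a list adjusted p of 2.67e-21 in camera, 0.256 with an estimated correlation and 0.0427 in fry. Of them 6 were higher in the Kmt2d-/- clones. Among them was Col2a1, the type II collagen gene, at 22460 ± 2814 CPM (SD, n = 2) against 236.7 ± 104.2 CPM (SD, n = 3). This was a 94.9-fold difference (log2 fold change 6.57, SE 1.02, edgeR adjusted p = 0.0252). Papss2, which makes the sulfate donor for proteoglycans, rose from 1.60 ± 0.418 to 95.9 ± 17.5 CPM (log2 fold change 5.91, SE 0.68, edgeR adjusted p = 0.00883). The matrilin gene Matn4 rose from 0.484 ± 0.353 to 30.5 ± 18.5 CPM (5.98, SE 0.71, edgeR adjusted p = 0.0101). Frzb, a secreted Wnt antagonist of cartilage, was 28.7-fold higher (edgeR adjusted p = 0.0471), and Fgfr3, a receptor that restrains cartilage growth, was 9.75-fold higher (edgeR adjusted p = 0.0235). Fgfr3 was 6.07-fold higher without Kmt2d-/- clone 2, and the log2 fold change of Matn4 was 6.75 without Kmt2d+/+ clone 1 and 5.16 without Kmt2d-/- clone 1. In all, 290 of 15467 genes passed, 140 higher and 150 lower in the Kmt2d-/- clones. With the regional offset, chosen after the data were seen, 230 passed, 82 higher and 148 lower.

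Sox9, the transcription factor that directs chondrocyte differentiation (chromosome 11, 112782224 to 112787760), stood at 445 ± 50.8 CPM in the Kmt2d-/- clones and 146.7 ± 71.4 CPM in the Kmt2d+/+ clones. The difference did not pass (log2 fold change 1.60, SE 0.48, edgeR adjusted p = 0.118). Shox2, a homeobox gene of limb skeletal development (chromosome 3, 66971727 to 66981771), stood at 5.24 ± 5.89 against 39.0 ± 5.86 CPM and did not pass either (-2.89, SE 0.72, edgeR adjusted p = 0.0769). Shox2 stood at 1.08 and 9.41 CPM in Kmt2d-/- clones 1 and 2, and its log2 fold change was -2.05 without clone 1 and -5.17 without clone 2. It passed as lower in limma-voom (adjusted p = 0.0251) and in DESeq2 (adjusted p = 1.88e-04), and Sox9 passed as higher in DESeq2 (adjusted p = 0.0186). Over the alternatives the adjusted p ranged from 1.88e-04 to 0.281 for Shox2 and 0.0186 to 0.337 for Sox9. Among other regulators, Foxa2, a forkhead factor also active in maturing chondrocytes, rose from 0.70 ± 0.516 to 32.7 ± 0.748 CPM. Hoxd13, a patterning gene of the distal limb, rose from 0.069 ± 0.0935 to 7.02 ± 4.95 CPM (edgeR adjusted p = 0.034 and 0.0355). Syk, a tyrosine kinase of immune receptor signalling, was 58.9-fold higher, Gfra4, a co-receptor of the GDNF family, 168-fold higher, and Ramp1, a receptor activity-modifying protein, 312-fold higher (edgeR adjusted p = 0.00883, 0.0104 and 0.0359). Ramp1 stood at 37.1 and 2.04 CPM in Kmt2d-/- clones 1 and 2, and its fold was 32.3 without clone 1 and 592.1 without clone 2. Syk was 37.7-fold higher and Hoxd13 49.2-fold, in place of 98.1-fold, without Kmt2d-/- clone 2. Without Kmt2d+/+ clone 2, which held 12 counts of Hoxd13, 2 Kmt2d+/+ counts were left and its fold was 403.9. Gfra4 was 258-fold higher without Kmt2d+/+ clone 2, and Foxa2 79.9-fold in place of 46.8-fold without Kmt2d+/+ clone 1.

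Genes lower in the Kmt2d-/- clones included Ndn, an imprinted gene that encodes necdin, at 0.0825 ± 0.117 against 30.9 ± 7.77 CPM (log2 fold change -8.49, SE 1.00, edgeR adjusted p = 0.0101). Cox7b2, which encodes an isoform of a cytochrome c oxidase subunit, had 1 count over the 2 Kmt2d-/- libraries and 2524 over the 3 Kmt2d+/+ libraries at day 7, a ratio of 1331 (exact binomial 95% interval 238.7 to 52600). That count was in clone 1, and without clone 2 the ratio was 649.7 (116.5 to 25670). Ly6c1, a surface antigen gene, had 2 and 2998 counts, a ratio of 790.6 (exact binomial 95% interval 218.7 to 6531). Pla2g5, a secreted phospholipase gene, stood at 60.3 ± 19.5 CPM in the Kmt2d+/+ clones and 0.842 ± 0.728 CPM in the Kmt2d-/- clones. Xdh, the xanthine dehydrogenase gene, stood at 35.9 ± 18.0 and 1.13 ± 0.652 CPM (edgeR adjusted p = 0.00863 and 0.0233). Dkk3, of the Dickkopf family, fell by 4.67 on the log2 scale (edgeR adjusted p = 0.0182). Scx, a tendon transcription factor, fell by 1.58 and Plk2, a p53 target, by 2.21 (edgeR adjusted p = 0.0346 and 0.0355). When Kmt2d-/- clone 1 was left out, the log2 difference was -7.53 for Ndn and -5.47 for Pla2g5, and without clone 2 it was -7.52 for Pla2g5 and -5.73 for Xdh, in place of -6.15 and -4.98 with all clones. Kmt2d-/- clone 1 had no Ndn counts.

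Of the 25 measured cartilage matrix genes, 6 rose, 0 fell and 19 did not pass over all genes, while 20 rose when adjusted over the list alone. Their median log2 fold change was 3.29 and 23 of the 25 were positive (camera adjusted p = 2.67e-21). No camera call in any comparison held with an estimated correlation (here adjusted p = 0.256), while fry passed this list alone at day 7. Matn3 was 10.5-fold higher (edgeR adjusted p = 0.0346), and 6.30-fold without Kmt2d-/- clone 1. The 29 interferon response genes held 28 negative values, with a median of -2.70 (camera adjusted p = 3.49e-05, and adjusted p = 0.862 with an estimated correlation). No single member passed over all genes and 1 fell when adjusted over the list alone. Xaf1, the most abundant member, stood at 128 ± 148 against 321.2 ± 198.5 CPM. The mean of this list differed among clones of 1 genotype: it was 1.85, 6.94 and 4.98 log2 CPM in Kmt2d+/+ clones 1, 2 and 3 and 1.80 and 3.57 in Kmt2d-/- clones 1 and 2. Without Kmt2d+/+ clone 2 the list no longer passed (camera adjusted p = 0.066, with 3.63e-18 to 0.862 over the alternatives). G2 and M phase genes passed as higher (41 genes, median 0.21, camera adjusted p = 0.0311, and adjusted p = 0.862 with an estimated correlation). Of them 0 passed singly, over all genes or adjusted over the list alone. That list no longer passed without Kmt2d+/+ clone 3 (camera adjusted p = 0.196, with 0.0147 to 0.862 over the alternatives).

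**Figure D2:**
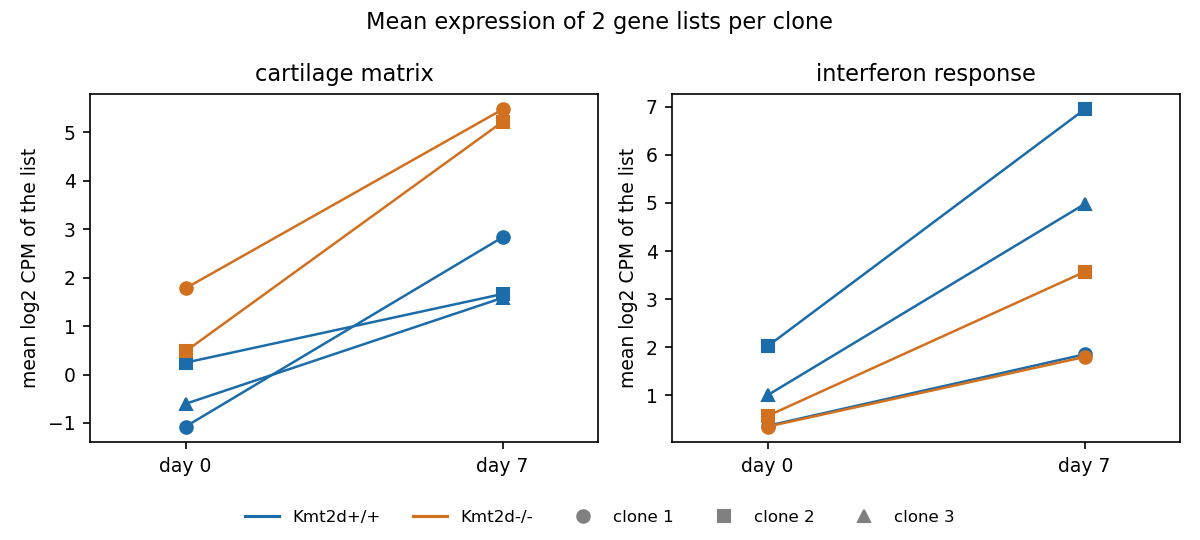
Mean log2 CPM of the cartilage matrix and interferon response genes at day 0 and day 7, with 1 line per clone coloured by genotype. At day 7 the cartilage matrix means were 1.58 to 2.84 in the Kmt2d+/+ clones and 5.22 to 5.47 in the Kmt2d-/- clones, and the interferon response means were 1.85 to 6.94 and 1.80 to 3.57.

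The other 24 tested lists did not pass at day 7. Among the 20 chondrogenic transcription factors 2 rose, Foxa2 and the ubiquitin ligase Wwp2 (4.65-fold, edgeR adjusted p = 0.0235). Adjusted over the list alone 5 rose and 2 fell (camera adjusted p = 0.294). Of 27 Wnt signalling genes Frzb rose and Dkk3 fell, and adjusted over the list alone 5 rose and 6 fell (camera adjusted p = 0.794). Of 17 FGF signalling genes Fgfr3 rose, and adjusted over the list alone 1 rose and 4 fell (camera adjusted p = 0.119). Id4, an inhibitor of basic helix-loop-helix factors, was the only one of 30 BMP and TGF-beta signalling genes to pass over all genes (log2 fold change 2.12, edgeR adjusted p = 0.0443). In that list 2 rose and 1 fell adjusted over the list alone, and the camera adjusted p was 0.402. Hoxd13 was the only one of 29 Hox genes to pass (2 adjusted over the list alone, camera adjusted p = 0.402). Plk2 was the only one of 18 p53 targets (2 fell adjusted over the list alone, camera adjusted p = 0.294). Ubr7 alone rose among 37 S phase genes, over all genes and adjusted over the list alone (log2 fold change 0.92, edgeR adjusted p = 0.0367, camera adjusted p = 0.402). Of 33 cytosolic ribosomal protein genes 2 rose, over all genes and adjusted over the list alone, among them Rpl5 (log2 fold change 0.89, edgeR adjusted p = 0.0346, camera adjusted p of the list 0.0631). Reads of ribosomal protein genes can be shared with their pseudogenes, so single values are uncertain.

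No member passed over all genes among hypertrophic and mineralizing chondrocyte genes (camera adjusted p = 0.794), hedgehog and PTHrP signalling (0.794), H3K4 methyltransferase complexes (0.484), hypoxia targets (0.0809), oxidative phosphorylation (0.325), cholesterol synthesis (0.338), the unfolded protein response (0.325) and matrix proteases and inhibitors (0.794). Adjusted over the list alone, these 8 lists held 0 passing genes in edgeR except 1 higher in the unfolded protein response and 1 higher and 2 lower among the proteases. In the hypertrophic, hedgehog and osteoblast lists the mean was negative while the median and the test were positive. In the neural list the median and mean were negative and the test positive, and in the protease list the median was positive and the mean and test negative.

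Markers of other cell types also passed in no list at day 7. The camera adjusted p was 0.836 for osteoblast, 0.535 for adipocyte, 0.911 for skeletal muscle, 0.108 for myofibroblast and smooth muscle, 0.325 for tendon and fibroblast, 0.402 for endothelial, 0.325 for immune cell and 0.918 for neural and glial markers. Of these, Scx alone passed over all genes, and adjusted over the list alone 1 osteoblast and 1 tendon gene fell. In the skeletal muscle list 1 rose and 1 fell. The 4 measured epithelial genes were too few for the list test and none passed (Cdh1 0.806 ± 0.0524 against 0.823 ± 0.475 CPM). The most abundant endothelial and immune markers, Pecam1 and Cd74, were at 4.95 ± 0.698 and 0.672 ± 0.814 CPM in the Kmt2d-/- clones and 6.92 ± 1.09 and 6.22 ± 2.90 CPM in the Kmt2d+/+ clones. Cd74 did not pass in edgeR but passed as lower in limma-voom (adjusted p = 0.0491) and DESeq2 (0.00134, with 0.00134 to 0.351 over the alternatives), as did Postn of the myofibroblast list in DESeq2 (0.00644, with 0.00644 to 0.289 over the alternatives).

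Some lists that did not pass at day 7 did so when a clone was left out. Without Kmt2d+/+ clone 1, the camera adjusted p was 3.3e-04 for FGF signalling, 0.0252 for myofibroblast, 0.0471 for tendon, 0.0417 for hypoxia and 0.00175 for ribosomal protein genes. It was 0.023 for hypoxia without Kmt2d+/+ clone 2, and 0.0374 for both the myofibroblast list and the unfolded protein response without Kmt2d-/- clone 1. Without Kmt2d-/- clone 2 it was 0.00368 for myofibroblast and 0.00341 for ribosomal protein genes. With each clone's regional level subtracted, a step chosen after the data were seen, it was 0.0328 for FGF, 0.00272 for hypoxia and 0.00236 for ribosomal protein genes. The adjusted p of these 6 lists ranged from 3.3e-04 to 0.998 over all the alternatives.

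Genes higher in the Kmt2d-/- clones were concentrated on parts of some chromosomes. Chromosome 12 held 39 of the 140 higher genes at day 7 (27.9%) but 3.23% of the genes tested (one-sided Fisher's exact test, adjusted p = 1.2e-24), and 49 of 181 at day 0 (adjusted p = 2e-30). From 40 Mb on, its 246 expressed genes had a median log2 difference of 0.67 at day 7 and 0.70 at day 0. Set against the mean of the Kmt2d+/+ clones, it was 0.64 to 0.74 in both Kmt2d-/- clones at both days and -0.05 to 0.08 in the Kmt2d+/+ clones. The first 20 Mb of chromosome 7 had medians of 0.70 and 0.64, and the first 60 Mb of chromosome 13 had 0.43 and 0.46. Clones 1 and 2 differed there, with 0.81 and 0.61 on chromosome 7 and 0.32 and 0.54 on chromosome 13 at day 7. These segments were chosen after the data were seen. Together these 3 segments held 5.42% of the tested genes, 68 of the 140 higher genes at day 7 and 78 of 181 at day 0. Ubr7 lies in the chromosome 12 segment, and Syk, Id4, Foxc1 and Diras2 in that of chromosome 13. When each clone's regional level was subtracted, the log2 difference at day 7 went from 0.92 (SE 0.17) to 0.27 (SE 0.13) for Ubr7. It went from 2.12 (SE 0.42) to 1.59 (SE 0.37) for Id4 and from 4.84 (SE 0.98) to 4.65 (SE 0.93) for Frzb. None of these 3 then passed (edgeR adjusted p = 0.346, 0.0751 and 0.0514, with 1.02e-04 to 0.439 over their alternatives). Genes lower in the Kmt2d-/- clones were concentrated on chromosome 4 at day 7 (21 of 150, Fisher's exact test, adjusted p = 0.0176) but did not pass there at day 0 (14 of 151, adjusted p = 0.42). In a distal cluster of 19 zinc-finger genes there, 11 fell, with Zfp980 at 0.14 ± 0.0617 against 9.79 ± 1.93 CPM (edgeR adjusted p = 7.96e-04). Besides these 11, Zfp984 passed just under the threshold, with a log2 difference of -2.28 and an edgeR adjusted p that rounds to 0.05. The zinc-finger genes are near-identical copies, so the split of reads among them is uncertain.

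**Figure D3:**
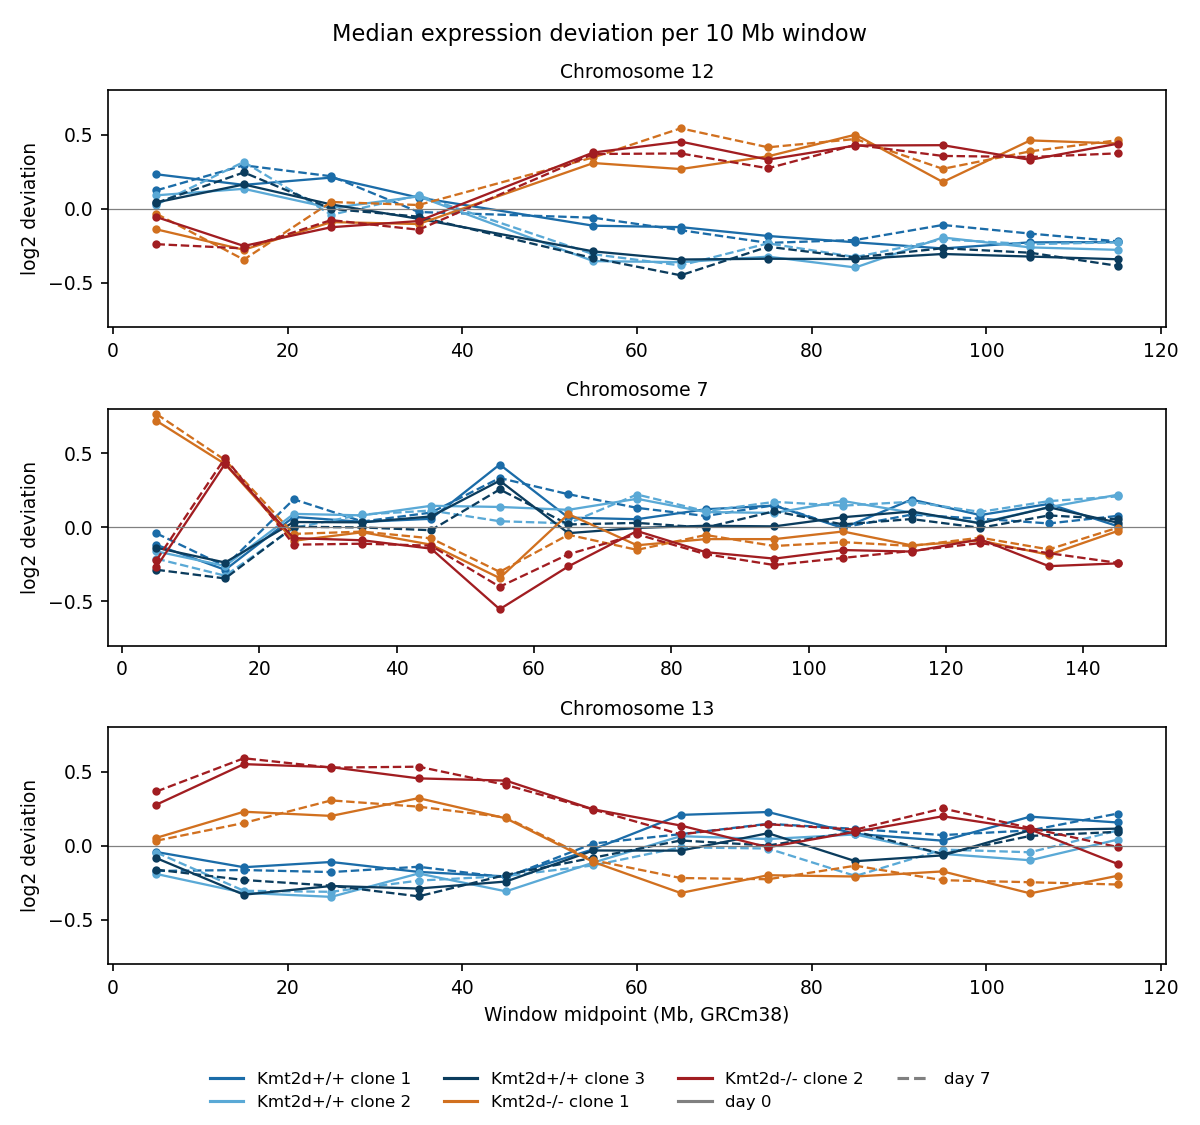
Median log2 deviation of expressed genes in 10 Mb windows along chromosomes 12, 7 and 13, each measured from the mean of all 5 clones at the same day, with 1 line per clone and day (solid for day 0, dashed for day 7). In the 7 windows of chromosome 12 from 50 Mb on, the Kmt2d-/- clones lie between 0.18 and 0.54 and the Kmt2d+/+ clones between -0.45 and -0.06, while in the first window of chromosome 7 Kmt2d-/- clone 2 lies at -0.27 and -0.22 and clone 1 at 0.72 and 0.77.

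The day 7 count was 32, 272 and 10 without Kmt2d+/+ clone 1, 2 or 3 and 27 and 70 without Kmt2d-/- clone 1 or 2. Of the 31 passing genes drawn by the naming rule, 8, 24 and 4 still passed without Kmt2d+/+ clone 1, 2 or 3. None changed sign when any 1 clone was left out. For its largest changes the rule took only genes whose clones did not overlap between genotypes, which largely fixed that outcome in advance. The fold of 16 of the 31 moved by over 1.5 times when some clone was left out. When only the day 7 libraries were fitted, 1 per clone, 15 of the 31 still passed and 16 did not.

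At day 0, before differentiation, the same comparison gave 332 genes, 181 higher and 151 lower in the Kmt2d-/- clones. Col2a1 was already higher, at 1670 ± 1221 against 15.3 ± 16.9 CPM (log2 fold change 6.77, SE 1.03, edgeR adjusted p = 0.023). Papss2 was also higher, at 9.53 ± 9.75 against 0.258 ± 0.102 CPM (5.18, SE 0.71, edgeR adjusted p = 0.019). Syk stood at 32.1 ± 2.81 against 0.0852 ± 0.0249 CPM, and Diras2, a Ras-family GTPase gene, at 18.2 ± 4.27 against 0.52 ± 0.44 CPM (edgeR adjusted p = 0.00461 and 0.0378). Lgr5, a receptor for R-spondins, was 21.5-fold higher, Igfbp2, an insulin-like growth factor binding protein, 24.1-fold, and Tgfb1 4.97-fold (edgeR adjusted p = 0.00999, 0.0409 and 0.0433). The log2 fold change of Col2a1 was 5.72 without Kmt2d-/- clone 1 and 7.38 without clone 2, and that of Papss2 was 3.33 and 5.97. Lgr5 was 11.7-fold higher without Kmt2d-/- clone 1. Without Kmt2d+/+ clone 2 the log2 fold change was 8.18 for Col2a1 and 6.04 for Diras2, in place of 5.11 for the latter. Sox9 stood at 165.1 ± 13.7 against 41.4 ± 25 CPM and Shox2 at 5.97 ± 1.58 against 27.6 ± 1.62 CPM, and neither passed (edgeR adjusted p = 0.0654 and 0.126). Sox9 passed without Kmt2d+/+ clone 2 (log2 fold change 2.59 in place of 1.99, edgeR adjusted p = 0.027), Shox2 without Kmt2d-/- clone 1 or 2 (0.0477 and 0.0353), and both in DESeq2 (adjusted p = 0.002 and 0.00691). The ranges over the alternatives were 0.002 to 0.6005 for Sox9 and 0.00691 to 0.6005 for Shox2.

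The homeobox genes Hoxd13 and Hoxd3 were also higher at day 0 (edgeR adjusted p = 0.0261 and 0.0305). Hoxd13 had 609 counts over the Kmt2d-/- libraries and 2 over the Kmt2d+/+ libraries, a ratio of 449.4 (exact binomial 95% interval 123.9 to 3719). Hoxd3 had 182 and 1 counts, a ratio of 268.6 (47.6 to 10670). In the Kmt2d+/+ and Kmt2d-/- clones, Ndn stood at 55.1 ± 18.0 and 0.0688 ± 0.0973 CPM, Cox7b2 at 10.9 ± 0.651 and 0.0833 ± 0.053 CPM and Pla2g5 at 49.5 ± 11.2 and 0.489 ± 0.281 CPM (edgeR adjusted p = 0.00804, 0.00191 and 0.0078). Ttbk1, a tau kinase gene, fell by 6.75, Dach2, a transcriptional cofactor gene, by 5.65 and Dkk3 by 4.68 on the log2 scale (edgeR adjusted p = 0.0282, 0.0206 and 0.019). Akr1c13 fell by 6.14 (edgeR adjusted p = 4.81e-04), though reads can be shared within the Akr1c family. The log2 difference was -8.62 for Ndn, in place of -9.57, and -9.36 for Ttbk1 without Kmt2d-/- clone 1. Without clone 2 it was -5.86 for Ttbk1 and -7.40 for Pla2g5, in place of -6.65 for the latter. Kmt2d-/- clones 1 and 2 held 130 and 479 of the counts of Hoxd13 and 35 and 147 of those of Hoxd3. The ratio of Hoxd13 was 688.9 (189.7 to 5705) without clone 1 and 197 (53.4 to 1644) without clone 2, and that of Hoxd3 422.8 (74.7 to 16810) and 106.1 (17.8 to 4308). Without Kmt2d+/+ clone 3 they were 279.4 (77.0 to 2312) and 167 (29.6 to 6632). All Kmt2d+/+ counts of both genes were in clone 2.

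Cartilage matrix genes were the only list to pass at day 0, with 21 of 25 positive. Their median was 0.93, or 0.89 with the member absent from a whole group at its bound (camera adjusted p = 3.55e-04, and adjusted p = 0.944 with an estimated correlation). Of them 2 rose over all genes, Col2a1 and Papss2, and 3 rose adjusted over the list alone. The list did not pass without Kmt2d-/- clone 1 (camera adjusted p = 0.094, with 2.3e-08 to 0.944 over the alternatives). The list means of Kmt2d-/- clones 1 and 2 were 1.78 and 0.48 log2 CPM against -1.08 to 0.25 in the Kmt2d+/+ clones. Among 20 chondrogenic transcription factors Foxc1 and Foxa2 were higher and Creb5 fell by 2.10, and adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.186). Foxa2 had no counts in the Kmt2d+/+ libraries and was at least 9.48-fold higher against a floor of 3 counts per library, or at least 3.24-fold without Kmt2d-/- clone 1 and 15.7-fold without clone 2. Ifit2 was the only one of 29 interferon response genes to pass, over all genes and adjusted over the list alone, and it was 2.01-fold higher. Of the 29, 27 were negative (camera adjusted p = 0.357). Of the 29 Hox genes 2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.186). In the H3K4 methyltransferase list the median and mean were negative and the test positive, in the osteoblast list only the mean was negative, and in the adipocyte list only the median was positive.

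Several lists that did not pass at day 0 did so without a clone. Without Kmt2d+/+ clone 1 the camera adjusted p was 0.0204 for BMP and TGF-beta signalling, 0.0198 for myofibroblast, 0.0148 for both G2 and M phase and interferon response, and 0.0218 for ribosomal protein genes. Ribosomal protein genes, negative in 26 of 33, also passed without Kmt2d+/+ clone 2 (0.0474) and under DESeq2's size factors (0.0394). Without Kmt2d-/- clone 1 the value was 2.27e-06 for myofibroblast and 9.44e-06 for G2 and M phase genes. Without Kmt2d-/- clone 2 it was 7.79e-04 for BMP, 0.0141 for S phase and 0.0409 for ribosomal protein genes. Over all the alternatives the adjusted p of these 6 lists ranged from 2.27e-06 to 0.982.

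With the regional levels subtracted, 213 genes passed at day 0, 86 higher and 127 lower in the Kmt2d-/- clones. Of these, 150 were among the 332 and 63 were new. Foxc1, Ubr7 and Ifit2 went from log2 differences of 0.85, 0.85 and 1.01 (SE 0.17 each) to 0.27, 0.20 and 0.71 (SE 0.16, 0.13 and 0.29) and did not pass. Foxa2, Atp9a, Eva1b and Igfbp2 did not pass either, although their differences stayed about as large, and their adjusted p moved just over the threshold. Those of Atp9a, Eva1b and Igfbp2 went from 7.40 (SE 1.45), 7.14 (SE 1.44) and 4.59 (SE 0.90) to 7.07 (SE 1.45), 7.27 (SE 1.44) and 4.56 (SE 0.91). With no regional level subtracted, the log2 difference of Atp9a was 8.30 and that of Eva1b 2.57 without Kmt2d-/- clone 1, and 4.55 and 8.11 without clone 2. Foxa2 had no counts in the Kmt2d+/+ clones, so its fitted difference, 8.12 (SE 1.51) before and 7.97 (SE 1.54) after, depends on the prior count and is no bound. The edgeR adjusted p was 0.223 to 0.432 for Foxc1, Ubr7 and Ifit2 and 0.0522 to 0.0626 for the other 4, with 3.76e-07 to 0.716 over their alternatives. The count was 16, 912 and 10 without Kmt2d+/+ clone 1, 2 or 3 and 68 and 38 without Kmt2d-/- clone 1 or 2, where 5, 24, 4, 11 and 11 of the 28 passing genes drawn by the rule still passed. The fold of 15 of the 28 moved by over 1.5 times when some clone was left out.

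Genotype differences were shared between days. Of the genes higher in the Kmt2d-/- clones, 56 passed at both days against 1.64 from independent lists, and of those lower, 67 against 1.46 (Fisher's exact test, p = 1.54e-73 and 1.55e-99). None passed in opposite directions. Across 15467 genes, which are not independent replicates, the log2 fold changes at the 2 days correlated with Pearson's r = 0.694. The same clones were measured at both days, so differences between clones are part of this overlap.

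Differentiation of the Kmt2d+/+ clones from day 0 to day 7 changed 786 genes, with 471 higher and 315 lower at day 7. Among the genes that rose, Matn1, a matrilin gene, went from 0.121 ± 0.0902 to 7.55 ± 3.37 CPM (SD, n = 3, log2 fold change 5.89, SE 0.63, edgeR adjusted p = 0.00741), and Fmod, the fibromodulin gene, from 2.92 ± 1.11 to 55.3 ± 25.9 CPM (4.24, SE 0.65, edgeR adjusted p = 0.0193). Dmp1, which encodes a mineralized matrix protein, went from 0.729 ± 0.414 to 59.2 ± 49.5 CPM (6.33, SE 1.36, edgeR adjusted p = 0.0381). The interferon-induced gene Isg15 went from 0.45 ± 0.535 to 127.4 ± 185 CPM and Stat2, which encodes a factor of interferon signalling, from 10.2 ± 1.23 to 96.6 ± 69.5 CPM (edgeR adjusted p = 0.0347 and 0.0222). Without Kmt2d+/+ clone 2 the log2 fold change was 7.14 for Isg15 and 2.46 for Stat2, in place of 8.12 and 3.25. It was 5.28 and 6.79 for Matn1 without clone 1 or 2 and 5.56 for Dmp1 without clone 3. Ccn2, a connective tissue growth factor gene, fell from 2469 ± 239.9 to 92.2 ± 33.5 CPM (log2 fold change -4.74, SE 0.52, edgeR adjusted p = 0.00741). Sox9 went from 41.4 ± 25 to 146.7 ± 71.4 CPM without passing (log2 fold change 1.82, edgeR adjusted p = 0.0528), and Shox2 from 27.6 ± 1.62 to 39.0 ± 5.86 CPM (edgeR adjusted p = 0.641). Sox9 passed as higher with a term for each clone (edgeR adjusted p = 0.0262), without Kmt2d+/+ clone 2 (log2 fold change 2.56, adjusted p = 0.028), with upper-quartile scaling, no filter or a mean of at least 5 CPM (0.0437 to 0.0489), in limma-voom (0.0436) and in DESeq2 (0.00102), with 0.00102 to 0.329 over the alternatives. Leaving out Kmt2d+/+ clone 1 gave a log2 fold change of 1.22 for Sox9, which did not pass.

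Also lower at day 7 were Ankrd1, an ankyrin repeat gene (8.68-fold, edgeR adjusted p = 0.0458), and Adam12, a metalloprotease gene (13.9-fold, edgeR adjusted p = 0.0202). So were Inhbb, an activin subunit gene (11-fold, edgeR adjusted p = 0.0347), and Timp3, a metalloprotease inhibitor gene (4.28-fold, edgeR adjusted p = 0.0202). Gbp11, a guanylate-binding protein gene, had 1 count over the day 0 libraries and 2570 over the day 7 libraries, a ratio of 1596 (exact binomial 95% interval 286.3 to 63080). That count was in clone 2, and without clone 3 the ratio was 818.1 (146.6 to 32340). Its paralog Gbp8 was 296.4-fold higher (edgeR adjusted p = 0.0236), and reads of these copies, as of Ifit3 and Ifit3b, can be shared. Car9, a carbonic anhydrase induced by hypoxia, was 99.1-fold higher and Slpi, a protease inhibitor gene, 91.9-fold higher (edgeR adjusted p = 0.0443 and 0.0321). At day 7 Car9 stood at 1.00, 14.98 and 1.06 CPM in clones 1, 2 and 3, and at day 0 it had 0, 6 and 1 counts. Slpi stood at 44.2, 4.51 and 3.63 CPM at day 7 in clones 1, 2 and 3, and its fold was 15.6 without clone 1 and 280.1 without clone 2. Inhbb was 16.9-fold lower without clone 2 and Gbp8 161.7-fold higher without clone 3. Without clone 1 the day 0 libraries held 3 counts of Gbp8.

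By list, 8 of 25 cartilage matrix genes rose (15 adjusted over the list alone). Their median log2 fold change was 2.76, or 2.60 with the member absent from a whole group at its bound (camera adjusted p = 3.12e-12, and adjusted p = 0.318 with an estimated correlation). Col9a1, a type IX collagen gene, and Ucma were among them (edgeR adjusted p = 0.0276 and 0.0378). Of 17 osteoblast markers 8 rose (10 adjusted over the list alone; camera adjusted p = 3.6e-07, and adjusted p = 0.199 with an estimated correlation). They included Smpd3, a sphingomyelinase gene of skeletal tissue, at 11.5-fold, and the near-identical osteocalcin genes Bglap and Bglap2, whose reads can be shared. Of 19 hypertrophic and mineralizing chondrocyte genes 6 rose (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.75e-06, and adjusted p = 0.199 with an estimated correlation). The phosphatase gene Phospho1 was 12-fold, the channel gene Panx3 19-fold and the parathyroid hormone receptor gene Pth1r 12.7-fold higher. Without clone 1 these folds were 5.01, 7.54 and 6.19, and that of Smpd3 was 5.48. Without clone 2 they were 21.8 for Phospho1, 43.1 for Panx3 and 17.5 for Smpd3. Of 21 cholesterol synthesis genes 8 rose (17 adjusted over the list alone) and all were positive (camera adjusted p = 1.41e-11, and adjusted p = 0.318 with an estimated correlation). Fdft1, the squalene synthase gene, was 2.67-fold and the sterol regulator Srebf2 1.71-fold higher.

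The 29 interferon response genes had a median of 4.02, and 5 rose over all genes against 26 adjusted over the list alone (camera adjusted p = 3.12e-12, and adjusted p = 0.388 with an estimated correlation). The list mean went from 0.37 to 1.85 log2 CPM in clone 1, from 2.02 to 6.94 in clone 2 and from 1.00 to 4.98 in clone 3. Of 26 hypoxia targets 4 rose (5 adjusted over the list alone), among them Bnip3, a mitophagy gene, at 2.71-fold (camera adjusted p = 0.0192, and adjusted p = 0.465 with an estimated correlation). Of 20 chondrogenic transcription factors 3 rose, Runx2, Foxc1 and Foxa2, the last by at least 9.89-fold against a floor of 3 counts per library, or 6.22-fold without clone 1. Adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.02, and adjusted p = 0.388 with an estimated correlation). The S phase genes fell as a list, with 33 of 37 negative and a median of -0.31. Of them 0 passed singly, over all genes or adjusted over the list alone (camera adjusted p = 8.05e-04, and adjusted p = 0.499 with an estimated correlation).

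Hedgehog and PTHrP genes passed with 3 of 14 rising, over all genes and adjusted over the list alone, among them the hedgehog receptor Ptch1 (2.66-fold; camera adjusted p = 0.0325, and adjusted p = 0.367 with an estimated correlation). Tendon and fibroblast markers passed with 1 of 11 rising, the growth factor receptor Pdgfra (3 adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.388 with an estimated correlation). Skeletal muscle markers passed with 1 of 7 rising (4 adjusted over the list alone; camera adjusted p = 0.0243, and adjusted p = 0.318 with an estimated correlation). That gene, the troponin Tnnt3, had 2 counts at day 0 and 46 at day 7, a ratio of 14.3 (exact binomial 95% interval 3.74 to 121.5). FGF signalling genes passed with 3 of 17 rising (4 adjusted over the list alone), including the feedback inhibitor Spry1 at 6.36-fold (camera adjusted p = 0.0498, and adjusted p = 0.476 with an estimated correlation). With a term for each clone the muscle and FGF lists did not pass (camera adjusted p = 0.0981 and 0.145, with 0.00675 to 0.499 and 2.41e-04 to 0.776 over their alternatives).

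Within lists that did not pass, 4 of 30 BMP and TGF-beta signalling genes fell, among them Smad7 and Smad6, which encode inhibitory Smads, by 2.05 and 1.25 on the log2 scale (5 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.124). Of 27 Wnt signalling genes 3 rose, with Wnt5a 13.2-fold higher (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.106). Of 18 p53 targets Plk2, Zmat3 and Aen fell and 2 rose, including the cell cycle inhibitor Cdkn1a at 13.6-fold, or 6.72-fold and 36.5-fold without clone 1 or 2 (3 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.166). The test and the median of the protease list differed in sign, as did the median and mean of the BMP, endothelial, immune, neural, Hox and p53 lists.

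List calls of this comparison that changed without a clone were as follows. Chondrogenic factors and hypoxia targets did not pass without Kmt2d+/+ clone 1 (camera adjusted p = 0.109 and 0.111). Hedgehog, tendon, muscle and FGF genes did not pass without Kmt2d+/+ clone 2 (0.0714, 0.0547, 0.175 and 0.4485), nor muscle and FGF genes without its clone 3 (0.08 and 0.124). Over all the alternatives these 6 lists ranged from 1.45e-04 to 0.776. Myofibroblast markers passed without Kmt2d+/+ clone 3 (0.0495) and without Kmt2d-/- clone 1 or 2 (0.00474 and 0.00228). G2 and M phase genes passed without Kmt2d+/+ clone 2 (0.0228) and without Kmt2d-/- clone 1 or 2 (0.0423 and 0.0492). Wnt genes passed without Kmt2d+/+ clone 2 (0.045) and ribosomal protein genes without its clone 1 (0.00298). The adjusted p of these 4 lists ranged from 0.00228 to 0.9075 over all the alternatives.

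With a term for each clone, 2789 genes passed in place of 786, and 783 were shared. No gene passed in edgeR without Kmt2d+/+ clone 1 or without clone 3 (2115 and 1921 at an unadjusted p under 0.05), 862 passed without clone 2 and 517 without Kmt2d-/- clone 2. The fold of 24 of the 63 passing genes drawn by the naming rule moved by over 1.5 times when some clone was left out.

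In the Kmt2d-/- clones, differentiation changed 196 genes, with 104 higher and 92 lower at day 7. Among the genes that rose, the matrilin gene Matn1 went from 0.155 ± 0.0889 to 56.5 ± 16 CPM (SD, n = 2, log2 fold change 8.50, SE 0.83, edgeR adjusted p = 0.0114) and Matn4 from 0.286 ± 0.177 to 30.5 ± 18.5 CPM (6.73, SE 0.89, edgeR adjusted p = 0.0207). Il17b, a cytokine gene, had no counts at day 0 and was at least 163-fold higher at day 7 against a floor of 3 counts per library. Padi2, which encodes a protein deiminase, was 118.6-fold higher, Ucma, a cartilage matrix gene, 121.6-fold, and Tnni2, a troponin gene of fast muscle, 246.3-fold (edgeR adjusted p = 0.017, 0.0399 and 0.0317). Without clone 1 the log2 fold change of Matn1 was 9.49 and without clone 2 it was 7.68. Clone 2 had no counts of Tnni2 at day 0. Col2a1 averaged 1670 ± 1221 CPM at day 0 and 22460 ± 2814 CPM at day 7. Sox9 averaged 165.1 ± 13.7 and 445 ± 50.8 CPM (edgeR adjusted p = 0.26), and Shox2 5.97 ± 1.58 and 5.24 ± 5.89 CPM (edgeR adjusted p = 0.948). The log2 fold change of Shox2 was 0.40 without clone 1 and -2.17 without clone 2, and neither passed.

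Among the genes that fell were Ccn2, from 634.6 ± 527 to 25.5 ± 2.65 CPM (log2 fold change -4.64, SE 0.63, edgeR adjusted p = 0.0207). Pappa, a protease that cleaves insulin-like growth factor binding proteins, fell from 74.1 ± 66.8 to 2.06 ± 0.00987 CPM (-5.16, SE 0.74, edgeR adjusted p = 0.0232). Inhba, an activin subunit gene, was 14.2-fold lower, Rgs4, a regulator of G-protein signalling, 19.7-fold, and Gprin3 13.3-fold (edgeR adjusted p = 0.0207, 0.0207 and 0.017). Without clone 1 the log2 fold change was -3.48 for Ccn2 and -3.70 for Pappa, and Inhba was 6.75-fold and Rgs4 9.85-fold lower. Without clone 2 it was -5.88 for Pappa, and Rgs4 was 53.5-fold lower.

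Of 25 cartilage matrix genes 7 rose (19 adjusted over the list alone), with 24 positive and a median of 4.48 (camera adjusted p = 3.26e-29, and adjusted p = 0.13 with an estimated correlation). Fmod was 41.7-fold and Matn3 30.9-fold higher (edgeR adjusted p = 0.031 and 0.0305), and Fmod was 67.5-fold higher without clone 1. Osteoblast markers passed with 2 of 17 rising, Bglap and Bglap2 (6 adjusted over the list alone; camera adjusted p = 1.08e-07, and adjusted p = 0.223 with an estimated correlation). Hypoxia targets passed with 24 of 26 positive and 0 rising over all genes (2 adjusted over the list alone; camera adjusted p = 9.38e-06, and adjusted p = 0.321 with an estimated correlation). Cholesterol synthesis genes were positive in 21 of 21, with 0 rising over all genes and 3 adjusted over the list alone (camera adjusted p = 2.12e-06, and adjusted p = 0.373 with an estimated correlation). Hypertrophic and mineralizing chondrocyte genes passed with 0 of 19 passing singly (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.31e-04, and adjusted p = 0.223 with an estimated correlation). The 29 interferon response genes had a median of 2.69 and 0 passing singly, over all genes or adjusted over the list alone (camera adjusted p = 1.66e-05, and adjusted p = 0.54 with an estimated correlation). The list mean went from 0.35 to 1.80 log2 CPM in clone 1 and from 0.57 to 3.57 in clone 2.

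Genes of oxidative phosphorylation (33 of 36 positive, median 0.34) and cytosolic ribosomal proteins (30 of 33, median 0.33) rose as lists with 0 members passing singly, over all genes or adjusted over the list alone. Each had a camera adjusted p of 8.63e-04, with adjusted p = 0.373 and 0.54 with an estimated correlation. Chondrogenic transcription factors passed with 0 of 20 rising over all genes (1 adjusted over the list alone; camera adjusted p = 0.0445, and adjusted p = 0.455 with an estimated correlation). They did not pass with a term for each clone (camera adjusted p = 0.0714, with 0.00345 to 0.616 over the alternatives). The list of BMP and TGF-beta signalling fell, with Smad7, Smad9 and Smad6 passing singly (3 rose and 7 fell adjusted over the list alone). Its median was -0.32, or -0.20 with the member absent from a whole group at its bound (camera adjusted p = 0.00736, and adjusted p = 0.223 with an estimated correlation). Tendon and fibroblast markers did not pass (camera adjusted p = 0.0581) but did with a term for each clone (0.00436, with 0.00205 to 0.502 over the alternatives). Among the other lists, Tnnt3 was at least 23.9-fold higher, Wnt5a 11.2-fold and Fgfr1 3.32-fold, and Plk2 fell by 2.54. Wnt5a was 21.2-fold and 6.26-fold higher without clone 1 or 2. The FGF list had a negative median with a positive mean and test, the adipocyte list a negative median and mean with a positive test, and the H3K4, protease and p53 lists medians, means and tests of mixed sign.

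Leaving out a clone changed several of these list calls. Without Kmt2d-/- clone 1 the ribosomal and BMP lists did not pass (camera adjusted p = 0.294 and 0.107), and without clone 2, or Kmt2d+/+ clone 2, the chondrogenic factors did not (0.237 and 0.0559). Over all the alternatives these 3 lists ranged from 2.19e-05 to 0.83. The direction of the cell cycle lists depended on which Kmt2d-/- clone was kept. With clone 2 as the remaining one, the S phase and G2 and M phase lists passed as lower (1.8e-07 and 1.86e-05). With clone 1 as the remaining one, G2 and M phase genes passed as higher (0.00952). The unfolded protein response passed without clone 1 (6.26e-04), and myofibroblast (2.29e-07), tendon (0.0349), protease (0.0316) and p53 genes (0.00952) without clone 2. Tendon markers also passed without Kmt2d+/+ clone 1 (0.00205) and muscle markers without its clone 3 (0.0398). For these 8 lists the alternatives gave an adjusted p of 1.8e-07 to 0.977.

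With a term for each clone, 862 genes passed in place of 196, with 191 shared. In edgeR, 0 genes passed without Kmt2d-/- clone 1 (1353 at an unadjusted p under 0.05), 22 without clone 2, 90 without Kmt2d+/+ clone 1, 0 without its clone 3 (1772 unadjusted) and 0 when only the 4 Kmt2d-/- libraries were fitted (1979 unadjusted). The fold of 16 of the 33 passing genes drawn by the naming rule moved by over 1.5 times when some clone was left out.

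The last comparison asked whether the change from day 0 to day 7 differed between genotypes. By gene, 0 of 15467 passed in edgeR, and 568 had an unadjusted p under 0.05. In DESeq2 22 genes passed, and in limma-voom 0. Lbh, a transcriptional cofactor gene, had the smallest p, with a log2 difference of 1.70 (SE 0.24, edgeR adjusted p = 0.913), followed by Nrn1 (-1.59, SE 0.28), Cdkn2b (-1.88, SE 0.35), Sdk2 (2.16, SE 0.40) and Vwa5a (-1.30, SE 0.26), each with an edgeR adjusted p of 1. The log2 difference was -0.20 for Col2a1 (SE 1.24), -0.39 for Sox9 (SE 0.69) and -0.68 for Shox2 (SE 0.91). That of Sox9 was 0.21 without Kmt2d+/+ clone 1 and -1.13 without clone 2, and that of Shox2 was -0.09 without Kmt2d-/- clone 1 and -2.67 without clone 2, none of which passed.

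By list, 4 passed, and in edgeR 0 of their members passed over all genes. Cartilage matrix genes passed as more positive in the Kmt2d-/- clones, with a median difference of 0.77, 19 of 25 positive and 1 higher adjusted over the list alone (camera adjusted p = 1.17e-08, and adjusted p = 0.671 with an estimated correlation). Cytosolic ribosomal protein genes were positive in 33 of 33 with a median of 0.40 (camera adjusted p = 4.04e-11, and adjusted p = 0.671 with an estimated correlation), and oxidative phosphorylation genes in 34 of 36 with a median of 0.21 (camera adjusted p = 8.9e-04, and adjusted p = 0.671 with an estimated correlation). Adjusted over the list alone, 0 genes of either passed. Interferon response genes were negative in 25 of 29 with a median of -1.42 and 1 lower adjusted over the list alone (camera adjusted p = 1.37e-05, and adjusted p = 0.901 with an estimated correlation). Without Kmt2d+/+ clone 2 the interferon list did not pass (camera adjusted p = 0.0608), nor did oxidative phosphorylation without Kmt2d-/- clone 1 (0.0903). Over the alternatives these ranged from 2.65e-17 to 0.97. Within clones the genotypes overlapped in 3 of the 4 lists. The mean of the cartilage matrix genes changed by 3.91, 1.42 and 2.19 log2 CPM in Kmt2d+/+ clones 1, 2 and 3 and by 3.69 and 4.74 in Kmt2d-/- clones 1 and 2. That of interferon response genes changed by 1.49, 4.92 and 3.97 and by 1.45 and 3.00. That of oxidative phosphorylation genes changed by 0.21, -0.02 and 0.09 and by 0.42 and 0.18. Ribosomal protein genes did not overlap, at 0.07, -0.08 and -0.38 and at 0.47 and 0.13. In the osteoblast, skeletal muscle, myofibroblast, unfolded protein and p53 lists the median, mean and test differed in sign.

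Other lists passed in the interaction when a clone was left out. S phase and G2 and M phase genes passed as more positive in the Kmt2d-/- clones without its clone 2 (camera adjusted p = 5.86e-09 and 9.23e-08) or without Kmt2d+/+ clone 2 (0.00104 and 0.0331). Without Kmt2d-/- clone 1 they passed in the opposite direction (0.0398 and 0.0111). Myofibroblast markers also passed in opposite directions without Kmt2d-/- clone 1 and without clone 2 (1.37e-04 and 8.1e-04). Cholesterol synthesis passed without Kmt2d+/+ clone 1 or 3 (0.0236 and 0.00482) and without Kmt2d-/- clone 2 (3.24e-04). Hypoxia targets passed without Kmt2d+/+ clone 1 (0.00306) and without Kmt2d-/- clone 1 (0.0227). FGF genes passed without Kmt2d+/+ clone 1 (0.0338), hypertrophic genes without its clone 2 (0.00643), the unfolded protein response without Kmt2d-/- clone 1 (1.37e-04), and BMP and Wnt genes without its clone 2 (0.00161 and 0.031). Over all the alternatives these 10 lists ranged from 5.86e-09 to 0.996.

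Calls of both genotypes overlapped: 76 genes rose and 60 fell in both against 3.17 and 1.87 from independent lists. The log2 fold changes correlated with Pearson's r = 0.679 over 15467 genes, which are not independent replicates. Of the 786 genes that changed in the Kmt2d+/+ clones, 97.5% had the same sign in the Kmt2d-/- clones.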

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

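In this part, the tests of scaling, with regional levels subtracted and of single clones were chosen only after the results were seen. That of scaling replaced one in which other scalings moved hardly any gene, and the test with matched genes, first 1 test of both lists, was separated by list and given a bootstrap bound after its medians were seen. In 4 gene lists the change from day 0 to day 7 passed as different between genotypes, and in 5 of the 147 named genes every clone of a genotype moved against every clone of the other.

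Cartilage matrix genes went from a mean of -0.48 ± 0.67 log2 CPM (SD, n = 3) to 2.03 ± 0.70 in the Kmt2d+/+ clones and from 1.13 ± 0.92 (SD, n = 2) to 5.35 ± 0.18 in the Kmt2d-/- clones (limma camera adjusted p of the interaction = 1.17e-08). Ribosomal protein genes went from 7.84 ± 0.08 to 7.71 ± 0.19 and from 7.60 ± 0.06 to 7.91 ± 0.19 (limma camera adjusted p = 4.04e-11). Oxidative phosphorylation genes went from 5.96 ± 0.07 to 6.06 ± 0.07 and from 5.87 ± 0.09 to 6.17 ± 0.08 (limma camera adjusted p = 8.9e-04). Interferon response genes went from 1.13 ± 0.83 to 4.59 ± 2.57 and from 0.46 ± 0.16 to 2.68 ± 1.25 (limma camera adjusted p = 1.37e-05). With an estimated correlation these adjusted p were 0.671, 0.671, 0.671 and 0.901. Within clones the change overlapped between genotypes in all of these lists except the ribosomal one, with cartilage matrix genes rising by 3.91 in Kmt2d+/+ clone 1 and by 3.69 in Kmt2d-/- clone 1.

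Cdkn2b, which encodes an inhibitor of cyclin-dependent kinases, moved in opposite directions in the genotypes. Its log2 change was 1.02, 0.74 and 1.26 in Kmt2d+/+ clones 1, 2 and 3 and -1.42 and -0.40 in Kmt2d-/- clones 1 and 2. The interaction was -1.88 on the log2 scale, which did not pass in edgeR (adjusted p = 1) and passed in DESeq2 (adjusted p = 0.0119). In the other 4 genes the interaction passed neither in edgeR (adjusted p = 1 each) nor in DESeq2. It was -2.87 for Xdh and 0.42 for Atp5b, an ATP synthase subunit gene. For Cox7b2 and Hoxd3 it was fitted as -3.05 and -4.24, values that depend on the prior count because a group held few counts. Over all 15467 genes 755 (4.88%) showed such opposite moves, where independent equal chances of either direction would give 6.25%.

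The cartilage matrix list also passed as higher in the Kmt2d-/- clones at day 7, with 6 of 25 genes passing singly. Its median log2 difference was 3.29 (camera adjusted p = 2.67e-21, 0.256 with an estimated correlation and 0.0427 in fry). Scaling driven by a few abundant genes is argued against, since a library's factor moves all genes alike and the list's median lay 3.31 above that of all genes tested, its lower quartile 2.08 above. Gains of chromosome segments as its whole source are argued against too, since the median was 3.32 with regional levels subtracted. The 10 splits of the 5 day 7 clones into 3 and 2 are too few for a share under 0.05. The share was 0.1, with a difference of list means of 3.32 by genotype and 2.89 in the highest other split, so clone-to-clone variation and a response to the loss of the Kmt2d domain, a candidate explanation, cannot be told apart with 2 mutant clones.

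The ribosomal protein and oxidative phosphorylation lists had median interactions of 0.40 and 0.21. Genes outside the lists matched on GC content, exon length and expression had medians of 0.148 (bootstrap 95% interval 0.112 to 0.230, 148 genes) and 0.103 (0.0305 to 0.165, 171 genes). Each interval includes 0.5 of its list's own median (0.20 and 0.11), the bound set for this test, so an effect of such gene properties and one of the genotype cannot be told apart for either list. A single clone as the source of the ribosomal result is argued against, since the highest camera adjusted p with a clone left out was 0.00327. For oxidative phosphorylation a single clone may be the source, since the list did not pass without Kmt2d-/- clone 1 (limma camera adjusted p = 0.0903, with 1.34e-04 to 0.97 over the alternatives).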

How the results depend on the processing

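The fits with regional levels subtracted and with a term for each clone plus an estimated correlation were chosen only after the results were seen. Over the alternatives, named genes kept their direction and side of the threshold in 3414 cases, no longer passed in 836 and newly passed in 42. Another 58 changed sign without passing either way, and none reversed. For its largest changes the naming rule took only genes whose clones did not overlap, which largely fixed their sign without a clone. Gene lists kept their call in 1102 cases, lost it in 98, gained it in 59, changed sign without passing in 85 and reversed in 4. Where leaving out a Kmt2d-/- clone left 1 in an arm, that lone sample was assumed to vary like the other groups. In the shallowest library (35792709 counts) depth put levels under 0.0838 CPM below the floor of 3 counts.

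With glmTreat, which by construction asks for a fold above 1.5, 51 genes passed for genotype at day 7, 62 at day 0, 97 for differentiation of Kmt2d+/+ and 58 for that of Kmt2d-/- clones, in place of 290, 332, 786 and 196. DESeq2 gave 1577, 1607, 2240 and 1009, and 22 for the interaction in place of 0 in edgeR (568 unadjusted). Of the named genes it newly passed Postn and Cd74 at day 7, Lpl, Tnc, Cd74 and Timp2 at day 0, Hcfc1, Postn, Cdh1 and Hoxb9 in Kmt2d+/+ and Postn, Hoxb9 and Timp2 in Kmt2d-/- differentiation, besides Sox9, Shox2 and the interaction genes given above. limma-voom gave 533 at day 7, and flow-cell run 2 alone 184. With regional levels subtracted 213 passed at day 0 (86 higher, 127 lower, 150 shared, 63 new) and 230 at day 7 (82 higher, 148 lower, 160 shared, 70 new). With only the libraries of the groups compared, 55, 9 and 0 passed for day 7, day 0 and differentiation of Kmt2d-/- clones (1979 unadjusted in edgeR). These fits have fewer libraries to estimate the spread, and the genotype fits among them hold 1 library per clone. The main fit counts a clone's libraries at its 2 days as independent, although their deviations correlated with r = 0.446 to 0.645. Its genotype counts of 290 and 332 therefore lean on libraries of 1 clone taken as separate replicates. Apart from glmTreat, the cause was not tested. The overlap of genotype calls at day 7 and day 0 was 586 genes at an unadjusted p under 0.01, a looser threshold, in place of 123.

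Leaving out 1 clone at a time, with fewer samples, gave 10 to 272 genes at day 7, 10 to 912 at day 0, 0 to 862 for Kmt2d+/+ and 0 to 183 for Kmt2d-/- differentiation. For the interaction it gave 0 in edgeR each time (284 to 1021 unadjusted). It gave 2 to 8 lists at day 7, 1 to 6 at day 0 and 5 to 10 for the interaction.

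With an estimated correlation limma's camera passed 0 lists in place of 3, 1, 12, 10 and 4 for day 7, day 0, Kmt2d+/+ and Kmt2d-/- differentiation and the interaction (1, 0, 3, 4 and 0 unadjusted). limma's fry passed 1, 0, 7, 1 and 0 (3 unadjusted at day 0 and 0 for the interaction). DESeq2's size factors gave 2 lists at day 0, and regional levels subtracted gave 6 at day 7. The cause was not tested. The reversed lists were G2 and M phase in Kmt2d-/- differentiation (camera adjusted p of 1.86e-05 to 0.53 with a clone left out) and, in the interaction, G2 and M phase (9.23e-08 to 0.996, with 0.0111 without Kmt2d-/- clone 1), S phase (5.86e-09 to 0.977, with 0.0398 without that clone) and myofibroblast markers (1.37e-04 to 0.996, with 8.1e-04 without Kmt2d-/- clone 2).

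With a term for each clone as replicate block, paired across days, 2789 genes passed for Kmt2d+/+ and 862 for Kmt2d-/- differentiation and 0 for the interaction in edgeR (1286 unadjusted). The cause of the rise was not tested. All 63 and 33 passing genes drawn by the naming rule kept their calls. Lists passing were 10, 10 and 4, and 0, 0 and 0 with an estimated correlation too (0, 2 and 0 unadjusted). Of the named genes, Sox9, Hcfc1, Postn and Hoxb9 newly passed in Kmt2d+/+ and Lpl, Postn, Hoxb9 and Timp2 in Kmt2d-/- differentiation. Beyond these and the list calls given with those comparisons, this block changed no other call of a named gene or list. Clone numbers are only names and do not pair the genotypes. Same-numbered clones correlated at -0.275 and -0.292 at day 0 and -0.004 and -0.059 at day 7. Deviations of the 2 Kmt2d-/- clones mirror each other, so the signs of these values cannot tell whether clones pair. Kmt2d+/+ clone 2 and Kmt2d-/- clone 1 share the name 10-7 in the labels, and what it marks is not given in the sources used here. They correlated at 0.2915 at day 0 and 0.0586 at day 7, the values of Kmt2d+/+ clone 2 with Kmt2d-/- clone 2 with the sign turned. The name 10-7 is the only shared one, so a paired genotype difference would rest on that pair alone, and none was fitted. Clone numbers as a replicate block left 28 genes at day 7 and 0 at day 0 in edgeR (995 unadjusted). That fit used only the libraries of the groups compared, which gave 55 and 9 without the block.

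Counts within 1.5 times of the main one under the other scalings and filters and run 1 alone were 217 to 275 at day 7 and 229 to 338 at day 0. The alternatives for normalized units and for transcripts did not apply to gene-level estimated counts and were not run.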

Other observations

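The tests of copy number, of windows and of the genotype in this part were chosen only after the results were seen, and Prkg2 and Mgp were picked after their values were seen. Of the 22 genes that passed the interaction in DESeq2, 9 had a more positive and 13 a more negative change in the Kmt2d-/- clones, and 0 passed in edgeR (568 genes at an unadjusted p under 0.05). Prkg2, a cGMP-dependent kinase needed in the growth plate, went from 33.2 ± 7.07 to 29.3 ± 9.16 CPM in the 3 Kmt2d+/+ clones and from 16.5 ± 3.17 to 68.1 ± 20.1 CPM in the 2 Kmt2d-/- clones (DESeq2 adjusted p = 0.0161). Mgp, the matrix Gla protein, an inhibitor of calcification, went from 2.26 ± 2.03 to 148.5 ± 61.0 CPM and from 19.5 ± 2.92 to 76.6 ± 48.8 CPM (DESeq2 adjusted p = 0.0291). Sdk2, a cell adhesion gene, went from 52.1 ± 15.5 to 61.6 ± 8.90 CPM and from 6.93 ± 1.71 to 36.6 ± 6.46 CPM (DESeq2 adjusted p = 0.00624). Lbh went from 32.4 ± 3.81 to 40.7 ± 3.52 CPM and from 14.6 ± 1.82 to 59.5 ± 4.73 CPM (DESeq2 adjusted p = 5.25e-06).

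On the second principal component (23.7% of the variance) the Kmt2d+/+ libraries scored -2.1 to 50 and the Kmt2d-/- libraries -50.5 to -14.7. On the third Kmt2d+/+ clone 2 scored 42.3 and 35.8 and the other Kmt2d+/+ libraries -34.1 to -9.68. In the zinc-finger cluster of chromosome 4, 19 of 19 genes had negative log2 differences at day 7 and 18 at day 0, with medians of -4.52 and -3.78. Chromosome 19 had a median of 0.35 at day 7. Set against the mean of the Kmt2d+/+ clones, it was -0.30 in Kmt2d+/+ clone 2 and 0.40 and 0.35 in Kmt2d-/- clones 1 and 2.

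For the clustering of genotype differences in chromosome segments, GC content, gene length and expression level are argued against, since 1095 matched genes elsewhere had a median day 7 difference of -0.0513 (bootstrap 95% interval -0.0864 to -0.0235) against 0.67 on chromosome 12 from 40 Mb. Clonal copy-number differences are a candidate explanation, since each clone's medians over 245 windows of 10 Mb correlated between its days with r of at least 0.8755, against at most 0.653 between clones. A response to the Kmt2d genotype cannot be told apart from them, because in 78 windows a Kmt2d+/+ clone departed from the other Kmt2d+/+ clones by over 0.3 at both days, which shows only that such shifts arise without the genotype. Of those windows, clone 2 departed in 67, clone 1 in 17 and clone 3 in 16, 13 windows differed as much between clones 1 and 3 alone, and 36 by genotype. DNA was not measured. On the log2 scale 3 copies in place of 2 would give 0.585. Day 7 medians over all expressed genes were 0.67 on chromosome 12 from 40 Mb, 0.70 on the first 20 Mb of chromosome 7 and 0.43 on the first 60 Mb of chromosome 13. Of the 839 tested genes of these segments 68 passed as higher. A simulated gain of 1.5-fold called 0 of 482 genes in edgeR (127 unadjusted). That simulation changed only 50 other genes, while the real fit called 290. Its adjusted threshold was therefore stricter, and its count cannot be set against the 68.

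For differentiation of the Kmt2d+/+ clones, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 786 genes and the highest of the others 0 in edgeR, so 1 of the 10 splits gave as many. The other splits that also part all 3 clones' pairs gave 0 as well, and differ in that they mix days.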
